A study of Mus musculus with 17 samples.

How the data were processed

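Gene expression was measured by mRNA sequencing in brown adipose tissue, the heat-producing fat, of 17 mice, 1 library per mouse. The mice were wild type or homozygous knockouts of Nocturnin (gene symbol Noct) and were kept for 4 h at 22 °C or at 6 °C. Each genotype and temperature formed 1 group, taken from the sample labels: 4 wild types at 22 °C, 5 wild types at 6 °C, 4 knockouts at 22 °C and 4 knockouts at 6 °C. Replicates are different animals.

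The deposited count table holds raw read counts per gene symbol for 21982 genes. A deposited table from the authors holds RPKM values, which are reads scaled to gene length and to the library's counted reads. In the genes compared, dividing the deposited counts by the RPKM values and the column total gave the same gene length in every library, to a relative spread of at most 9.51e-15. The RPKM values are therefore the deposited counts scaled to the total count. Per the submitters' processing notes, STAR and HTSeq were used with the builds mm10 and GRCm38.p6. The notes give no versions, no annotation and no strand setting. Where genes overlap on opposite strands, reads of one gene can therefore have been counted for the other. No per-sample column was left unassigned.

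Library totals ran from 18410748 to 47598200 counts. Mitochondrially encoded genes took 43.4 to 57.3% of each library, and the 10 most counted genes took 50.7 to 62.1%. The reads carry no molecular identifiers, so intervals and floors that rest on counts cover counting error only. A gene with no count in a group was set against a floor of 3 counts over the group, and intervals are exact at a confidence level of 95%.

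Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 12486 genes, and libraries were scaled by TMM. One quasi-likelihood model was fitted to all 17 libraries with a mean per group and the labelled sex as an additive covariate, leaving 12 residual degrees of freedom. Sex was included because 2 of 9 wild types and 6 of 8 knockouts were labelled male. The contrasts were the cold response in wild type, the cold response in knockout, the genotype difference at each temperature, and the difference between the cold responses (knockout minus wild type). P values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05 and no minimum fold. Log2 fold changes are given ± SE of the fitted coefficient. Group levels are TMM-scaled read counts relative to library size (CPM), given as mean ± SD over animals.

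The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an addition is stated. The rule took Noct in every sample. For each comparison it then took up to 6 genes with the largest rise and up to 6 with the largest fall. These had to pass the threshold, reach a mean CPM of at least 5 in a compared group, have compared groups whose CPM values did not overlap, and carry neither a predicted nor a pseudogene name. For each list it took up to 4 passing members with the largest change, or up to 2 members with the highest level where none passed. Absence of overlap was not asked for the difference between the cold responses. Not every gene the rule took is described. Genes outside the rule are marked as chosen after their values were seen.

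The 27 fixed lists covered brown fat function, metabolism, the clock, stress responses and markers of other cell types, beside the sex-linked genes and the targeted gene. The 24 lists with at least 5 tested members were tested with camera from limma 3.58.1, which compares a list with all other genes, at a preset correlation between genes of 0.01. These p values were adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which tests whether a list's own genes move one way on balance, were run as alternatives. Counts of list members past the threshold are given over all tested genes and adjusted over the list alone.

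The alternatives were DESeq2 size factors within edgeR, no low-count filter, a filter of at least 1 CPM in 4 samples, and the Wald test of DESeq2 1.42.0. The model was also run with no sex term, with sex and the labelled age, with the replicate number as a block, on the compared groups alone, and on the majority sex of each genotype. Further alternatives were a test against a fold of 1.5 (glmTreat), limma-trend on log2 RPKM with a pseudocount of 1 or 0.1, and leaving out each library in turn. Leaving out mitochondrial genes, list tests without wild-type 22 °C replicate 2, leaving libraries out of the correlation of the cold responses, and the alternatives for the sex difference were added after the data had been seen. The replicate numbers did not pair the samples. Gene positions came from GENCODE vM21 on GRCm38, which held 98.5% of the tested genes.

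The procedure was tested on simulated counts at the same group sizes, with known changes in 200 genes per comparison. For the genotype difference at 22 °C, 58.2% of genes changed by a fold of 2 and 87.9% changed by a fold of 4 were recovered. For the difference between the cold responses the shares were 49.3% and 89.4%, and at a fold of 1.5 it was 8.96%. The adjustment is stricter where fewer genes pass, so these recovered shares can be too high where few genes differ. Among genes simulated without change, 3 to 6 were called per comparison by edgeR and 15 to 25 by DESeq2, of at least 12133.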

Results

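Messenger RNA of brown adipose tissue was sequenced from 17 mice labelled C57BL/6. Wild-type and Noct knockout littermates were single-housed without food for 4 h at 22 °C or 6 °C. The groups held 4 wild types at 22 °C (3 female, 1 male), 5 wild types at 6 °C (4 female, 1 male), 4 knockouts at 22 °C (1 female, 3 male) and 4 knockouts at 6 °C (1 female, 3 male). Library totals were 26921197 to 47598200 counts in wild types at 22 °C, 18410748 to 33663371 in wild types at 6 °C, 24823535 to 32929256 in knockouts at 22 °C and 27261943 to 30797852 in knockouts at 6 °C. Labelled ages ran from 11.14 to 23.57 without a unit, whereas the series text gives 10 to 20 weeks. The labels give no time of day. "Rose" and "fell" are used for an adjusted p below 0.05 over the 12486 tested genes.

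Noct encodes Nocturnin, a clock-controlled phosphatase of NADP(H) related to mRNA deadenylases, and lies on the plus strand of chromosome 3 (GRCm38, 51224447 to 51251644). Its level was 140 ± 35.6 CPM in wild types at 22 °C (91.5 to 176, n = 4) and 346 ± 81.7 CPM in wild types at 6 °C (238 to 457, n = 5). Knockouts held 13.2 ± 14.3 CPM at 22 °C (3.37 to 34.2, n = 4) and 22.6 ± 4.46 CPM at 6 °C (18.2 to 27.2, n = 4), which is 9.43% and 6.53% of the wild-type means. Which part of Noct the targeted allele removes is not given in the sources used here, so these shares are no measure of intact Noct mRNA. Every knockout library lay below every wild-type library. Noct rose in the cold in wild type by 1.33 ± 0.44 log2 (adjusted p = 0.0332), and in knockouts its value was 0.79 ± 0.47 (adjusted p = 0.257). These responses did not pass the test of their difference (-0.54 ± 0.63, adjusted p = 1). Without knockout 22 °C replicate 3, the knockout with the highest Noct level (34.2 CPM), Noct rose in knockouts as well (1.9, adjusted p = 0.0011). The call in wild type was lost without wild-type 22 °C replicate 1 (adjusted p = 0.0925), 2 (0.0763) or 3 (0.0676), and without wild-type 6 °C replicate 1 (0.074), 2 (0.0503) or 5 (0.0542), with log2 values between 1.18 and 1.38. It was also lost with the replicate block, with sex (1.24, adjusted p = 0.0841) or without (1.3, 0.0686), with the majority sex alone (1.33, 0.107), against a fold of 1.5 (0.278) and from log2(RPKM + 0.1) (1.12, 0.0719).

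**Figure D1:**
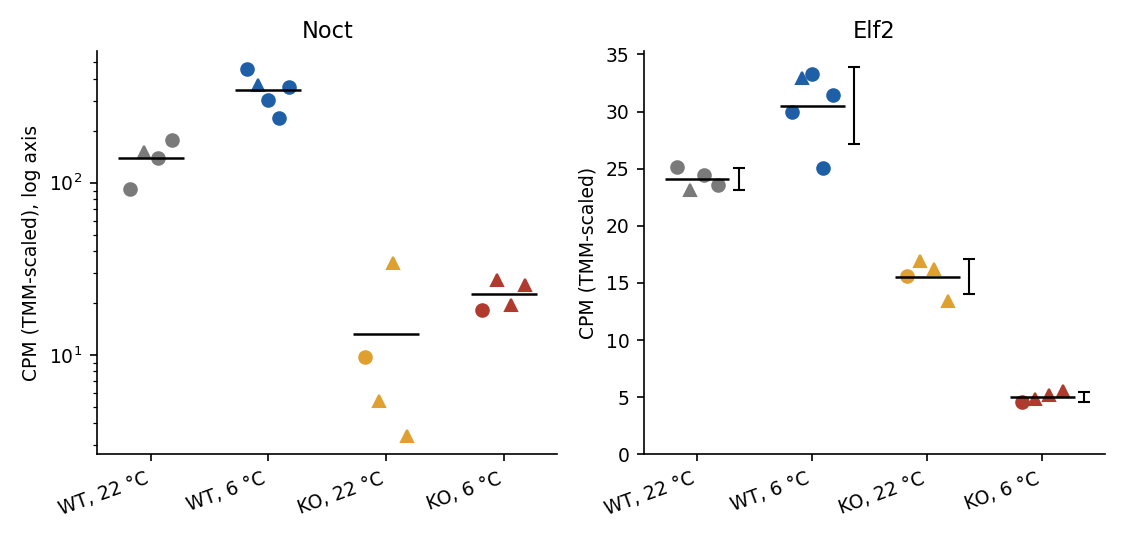
TMM-scaled read counts (CPM) of Noct (left, log axis) and Elf2 (right, linear axis) in each mouse, with circles for females, triangles for males, a line at each group mean and, for Elf2, a bar of 1 SD. Noct is at most 34.2 CPM in the knockouts and at least 91.5 CPM in the wild types, and Elf2 is lowest in knockouts at 6 °C, at 5.03 ± 0.42 CPM.

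The first comparison asked how wild-type brown fat responds to 4 h of cold. The heat-producing genes Ppargc1a, Dio2 and Ucp1 rose, as did most chaperone and glucocorticoid-responsive genes, while the lipogenic regulator Srebf1 and the adipokine Lep fell. Ppargc1a, a coactivator of mitochondrial and thermogenic genes, went from 204 ± 193 to 1172 ± 236 CPM (2.86 ± 0.35 log2, adjusted p = 3.96e-05, n = 4 and 5). Dio2, which makes active thyroid hormone in the tissue, went from 578 ± 216 to 2477 ± 520 CPM (2.17 ± 0.22, adjusted p = 1.61e-05). Ucp1, the uncoupling protein that releases heat, went from 4514 ± 622 to 6951 ± 812 CPM (0.63 ± 0.14, adjusted p = 0.00303). In all, 3450 of 12486 genes (27.6%) passed in edgeR, of which 1786 rose and 1664 fell, and 273 of the rises and 491 of the falls exceeded a fold of 2. Of the largest rises, the cytokine signalling suppressor Socs2 rose by 2.72 ± 0.41, the stress kinase Plk3 by 2.44 ± 0.46, the lysolipid transporter Mfsd2a by 2.41 ± 0.51 and the transcription factor Maff by 2.35 ± 0.35. Among the largest falls were those of the apelin receptor Aplnr (-3.61 ± 0.50), Klhdc7a (-2.90 ± 0.38), Kbtbd11 (-2.67 ± 0.27), the death ligand Tnfsf10 (-2.56 ± 0.31), the lactate receptor Hcar1 (-2.43 ± 0.44) and Rasl12 (-2.37 ± 0.28). For each of these 10 genes, every library at 6 °C lay on 1 side of every library at 22 °C, as the rule for named genes required.

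By list, 8 of 24 thermogenic genes rose and 4 fell in wild type (9 and 4 adjusted over the list alone). Beside Ppargc1a, Dio2 and Ucp1, glycerol kinase Gk rose by 1.55 ± 0.24, while the adrenoceptor Adrb1 fell by 1.01 on the log2 scale. Of 22 immediate-early and cAMP-responsive genes, 9 rose, with Atf3 at 2.71 ± 0.53, the phosphodiesterase Pde4d at 1.07 ± 0.15 and Per1 at 0.96 ± 0.26, and adjusted over the list alone 9 rose and 1 fell. Neither list passed camera (adjusted p = 0.0707 and 0.122), whereas by fry the thermogenic list passed (adjusted p = 0.00884) and the immediate-early list did not (0.127). Glycolysis and glucose uptake genes passed as a list (camera adjusted p = 0.0153, and adjusted p = 0.805 with an estimated correlation). This list did not pass by fry (adjusted p = 0.0561). Of its 21 members 4 rose on either adjustment, among them the phosphofructokinase Pfkp (1.32 ± 0.21), the glucose transporter Slc2a1 (0.84 ± 0.21) and Pgk1 (0.40 ± 0.11). By limma-trend on RPKM Pgk1 read 0.19 and did not pass with a pseudocount of 1 (adjusted p = 0.12) or 0.1 (0.122). In the tricarboxylic acid cycle, 1 of 24 genes rose over all genes, as did 1 of 38 nuclear-encoded oxidative phosphorylation subunits, and none passed adjusted over the list alone. None of 9 mitochondrially encoded subunits passed, and mt_Cytb read 0.14 ± 0.15.

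Lipid genes moved in both directions in wild type. In the fatty acid oxidation list, 4 of 25 genes rose and 1 fell (4 and 1 adjusted over the list alone), with Pdk4, which restrains glucose oxidation, at 0.91 ± 0.18. Of 17 fatty acid synthesis genes, 2 fell on either adjustment, and Srebf1 fell by 2.16 on the log2 scale. The synthesis enzymes Scd1 (0.20 ± 0.27) and Fasn (0.04 ± 0.27) did not pass. Of 26 triglyceride genes, 7 rose and 3 fell (8 and 5 adjusted over the list alone). The acyltransferase Gpam rose by 0.80 ± 0.13 and the droplet protein Plin2 by 0.89 ± 0.18, while the acyltransferase Dgat2 fell (-1.02 ± 0.18). In sterol synthesis, 3 of 21 genes rose (2 adjusted over the list alone), with Hsd17b7 at 0.74 ± 0.20.

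Clock genes also moved in both directions, with 9 of 19 rising and 4 falling in wild type (9 and 5 adjusted over the list alone). Per3 fell by 2.06 on the log2 scale (adjusted p = 4.63e-06), while Arntl rose by 1.71 ± 0.31, Nfil3 by 1.52 ± 0.16 and Per2 by 1.35 ± 0.24. Of 32 NAD(P)(H) genes, 4 rose and 3 fell (4 and 1 adjusted over the list alone), with the methyltransferase Nnmt at 1.25 ± 0.31 and Nmrk1 at -0.70 ± 0.17. Of 19 mRNA deadenylation genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone), and the deadenylase Parn fell by 0.59 on the log2 scale.

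Most chaperone and glucocorticoid-responsive genes rose in wild type. Of 12 heat-shock and cold-inducible genes, 10 rose on either adjustment (camera adjusted p = 7.82e-10, and adjusted p = 0.0684 with an estimated correlation). Hsph1 rose by 2.19 ± 0.29 and Hsp90aa1 by 1.91 ± 0.27. Hspa1a rose by 3.66 ± 0.54 and Hspa1b by 3.63 ± 0.62, but these near-identical paralogs share reads and their split is uncertain. Of 15 glucocorticoid-responsive genes, 13 rose (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 9.69e-06, and adjusted p = 0.0684 with an estimated correlation). Among them, the cell cycle inhibitor Cdkn1a rose by 1.76 ± 0.31, Fkbp5 by 1.60 ± 0.49 and the metallothionein Mt2 by 1.59 ± 0.36. In the unfolded protein and integrated stress response list, 7 of 22 rose and 2 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.0707), with Atf4 at 1.36 ± 0.18 and Dnajb9 at 1.09 ± 0.19. Of 7 tested cytokine and adhesion genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone). The fall, of Tnfaip3, was lost in several settings, such as with the replicate block and sex (-0.86, adjusted p = 0.0747) and with the majority sex alone (-0.60, 0.206).

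Markers of other cell types showed few passing members in wild type. None of 15 skeletal muscle genes passed, and their summed level ran from 32.0 to 884 CPM at 22 °C and from 52.1 to 1186 CPM at 6 °C. Of 8 white adipocyte genes, Lep fell (-3.05 ± 0.78, adjusted p = 0.00787), and adjusted over the list alone 1 rose and 4 fell. Of 12 macrophage genes 1 rose on either adjustment, Cd163 (1.04 ± 0.21). Of 11 endothelial genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone), with Esam at 0.63 ± 0.14 and Pecam1 at 0.53 ± 0.12. None of 11 fibroblast and 6 red cell genes passed on either adjustment. Of 7 nerve genes, 1 rose, the myelin gene Pmp22 (1.14 ± 0.18), and 1 fell on either adjustment. The 21 lists other than the heat-shock, glucocorticoid and glycolysis lists had camera adjusted p from 0.0707 to 0.988. In the fatty acid synthesis, deadenylation, muscle, macrophage, fibroblast and nerve lists the signs of median, mean and test differed.

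Wild-type 22 °C replicate 2 stood apart, with Ppargc1a at 493 CPM against 92.4 to 116 CPM in the other wild types at 22 °C. Without it 2947 genes passed, and 5 rather than 3 lists passed camera, the thermogenic list (adjusted p = 0.0188) and the stress response list (0.0377) included. With all libraries and an estimated correlation these 2 lists had camera adjusted p = 0.602 and 0.805. Scaling to total counts, from group means of log CPM without the sex term, moved the median of all genes from -0.027 to -0.226 log2. Of the genes called by limma-trend on log2(RPKM + 1), which changes the scaling and the test together, 22.0% were higher in the cold, against 51.8% in edgeR.

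**Figure D2:**
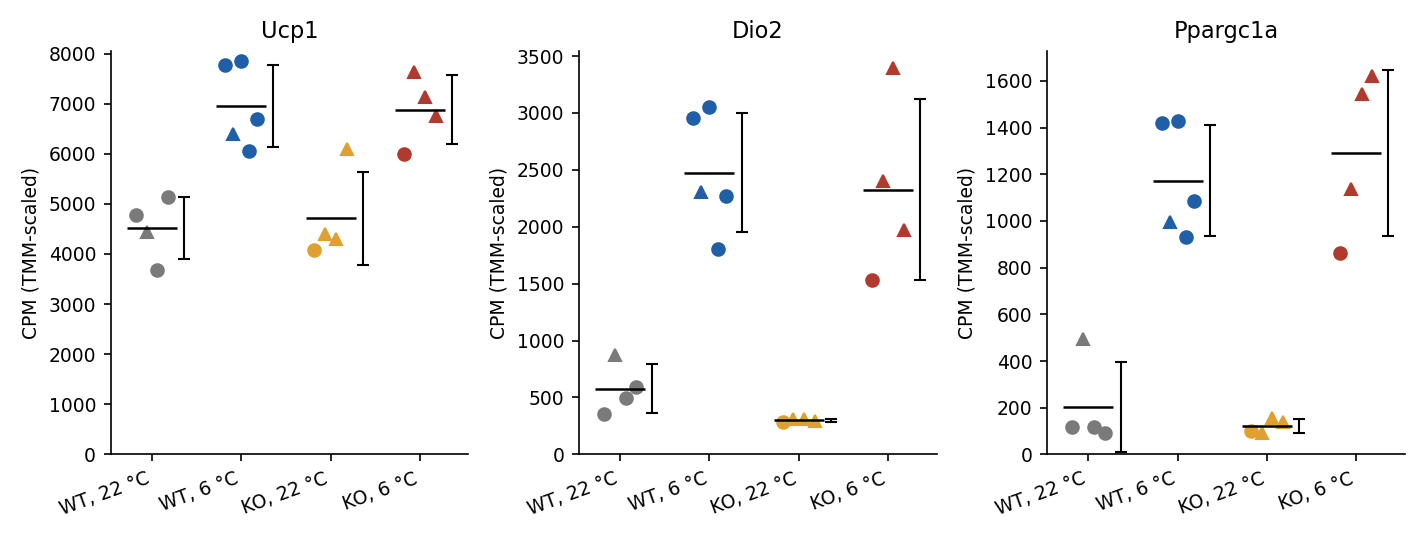
TMM-scaled read counts (CPM) of Ucp1, Dio2 and Ppargc1a in each mouse (circles female, triangles male), with a line at each group mean and a bar of 1 SD. Each gene rose in the cold in both genotypes, and wild-type 22 °C replicate 2, at 493 CPM, is the highest 22 °C library for Ppargc1a.

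The same question was put to the knockouts. The heat-producing genes Ppargc1a, Dio2 and Ucp1 and 8 of 12 heat-shock genes rose in the cold without Noct as well. Ppargc1a went from 121 ± 30.5 to 1292 ± 356 CPM (3.37 ± 0.35 log2, adjusted p = 1.89e-05, n = 4 and 4). Dio2 went from 299 ± 11.3 to 2324 ± 794 CPM (2.92 ± 0.24, adjusted p = 1.81e-06), and Ucp1 from 4716 ± 928 to 6879 ± 693 CPM (0.55 ± 0.14, adjusted p = 0.0119). With the majority sex alone Ucp1 read 0.54 and narrowly missed the threshold (adjusted p = 0.0511). In edgeR 2697 genes (21.6%) passed, with 1446 rises and 1251 falls, and 309 of the rises and 384 of the falls exceeded a fold of 2. Limma-trend on log2(RPKM + 1), which changes the scaling and the test together, called 975 genes higher and 1387 lower (41.3% higher, against 53.6% in edgeR). The largest rises included those of Plk3 (3.69 ± 0.51), the haem oxygenase Hmox1 (3.66 ± 0.61), Atf3 (3.44 ± 0.56), Mfsd2a (3.37 ± 0.54) and the junction protein Cldn1 (3.35 ± 0.42). The largest falls included those of Aplnr (-3.64 ± 0.54), Klhdc7a (-2.90 ± 0.41), Kbtbd11 (-2.61 ± 0.29), Rasl12 (-2.50 ± 0.31) and Bahcc1 (-2.42 ± 0.30).

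Of 24 thermogenic genes, 8 rose and 3 fell in knockouts on either adjustment (camera adjusted p = 0.0022, and adjusted p = 0.194 with an estimated correlation). By fry this list passed, as it did in wild type (adjusted p = 0.00117 in knockouts). Gk rose by 1.61 ± 0.25 and the potassium channel gene Kcnk3 by 1.18 ± 0.12. Of 22 immediate-early genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.000285, and adjusted p = 0.285 with an estimated correlation). Nr4a3 rose by 2.38 ± 0.46 and Pde4d by 1.49 ± 0.15. Heat-shock genes rose in 8 of 12 cases (10 adjusted over the list alone; camera adjusted p = 1.62e-07, and adjusted p = 0.136 with an estimated correlation), with Hsph1 at 1.98 ± 0.29 and Hsp90aa1 at 1.52 ± 0.27. Glucocorticoid-responsive genes rose in 10 of 15 cases (12 adjusted over the list alone; camera adjusted p = 3.9e-06, and adjusted p = 0.136 with an estimated correlation), with Cdkn1a at 1.79 ± 0.32 and Mt2 at 1.51 ± 0.37. In the stress response list, 6 of 22 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.0491, and adjusted p = 0.641 with an estimated correlation), with Atf4 at 1.72 ± 0.19. Of 12 macrophage genes, only Cd163 rose, by 0.99 ± 0.22, on either adjustment, and the list passed camera (adjusted p = 0.0491, and adjusted p = 0.907 with an estimated correlation). Without wild-type 22 °C replicate 2, camera adjusted p was 0.0527 for the stress response list and for the macrophage list, and with the replicate block and sex it was 0.0698 for the stress response list.

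Among metabolic lists in knockouts, 3 of 21 glycolysis genes rose on either adjustment, with Slc2a1 at 1.04 ± 0.23 and Pfkp at 0.92 ± 0.22. No member passed in the tricarboxylic acid cycle or nuclear-encoded oxidative phosphorylation lists, and 1 of 9 mitochondrially encoded genes fell, each on either adjustment. Fatty acid oxidation had 2 rises (1 adjusted over the list alone), with Pdk4 at 0.88 ± 0.19. Fatty acid synthesis had 2 falls on either adjustment, Srebf1 (-1.96 ± 0.33) and the lipase family gene Pnpla3 (-1.02 ± 0.24). Triglyceride genes had 7 rises and 1 fall (8 and 1 adjusted over the list alone), with the lipoprotein lipase Lpl at 0.87 ± 0.17, Gpam at 0.74 ± 0.13 and Dgat2 at -0.83 ± 0.20. Sterol synthesis had 2 rises on either adjustment. Clock genes had 6 rises and 5 falls (7 and 8 adjusted over the list alone), with Arntl at 1.79 ± 0.32, Per3 at -2.38 ± 0.19, Bhlhe40 at -1.91 ± 0.28 and Dbp at -1.80 ± 0.25. NAD(P)(H) genes had 3 rises and 2 falls on either adjustment, with Nnmt at 2.06 ± 0.33 and the dehydrogenase Idh1 at -0.70 ± 0.17. No deadenylation gene passed on either adjustment.

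Of 7 cytokine and adhesion genes, 3 rose and 1 fell in knockouts (4 and 1 adjusted over the list alone), with Icam1 at 1.38 ± 0.25. The fall, of Tnfaip3, was lost in many settings, such as with only the groups compared (-0.82, adjusted p = 0.13) and with the majority sex alone (-0.60, 0.268). Endothelial genes had 2 rises and 1 fall on either adjustment, and Tek fell by 0.50 on the log2 scale. The rises, of Esam and Pecam1, were lost in several alternatives, such as with only the groups compared (adjusted p = 0.0612 and 0.149). Pmp22 rose by 1.31 ± 0.19 among 7 nerve genes, and 1 of 8 white adipocyte genes fell, each on either adjustment. No muscle, fibroblast or red cell gene passed on either adjustment, and summed muscle levels ran from 65.9 to 1132 CPM at 22 °C and from 23.5 to 1572 CPM at 6 °C. The other 18 lists had camera adjusted p from 0.121 to 0.937. In the fatty acid oxidation, clock, NAD(P)(H), deadenylation, muscle and endothelial lists the signs of median, mean and test differed. Fitting the knockout groups alone left 1589 genes past the threshold, and the labelled males alone left 1647.

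Across the 12486 genes the cold responses of the genotypes, which share no libraries, correlated with Pearson's r = 0.807 and Spearman's rho = 0.793. Genes are not independent replicates, so no p is given. Of the genes that rose, 1184 did so in both genotypes, against 206.8 for independent lists, and 933 fell in both, against 166.7. Of the 4029 genes called in either genotype, 98.3% had the same sign in both. Elf2 alone was called in both with opposite signs, and 5 alternatives lost its call in wild type.

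**Figure D3:**
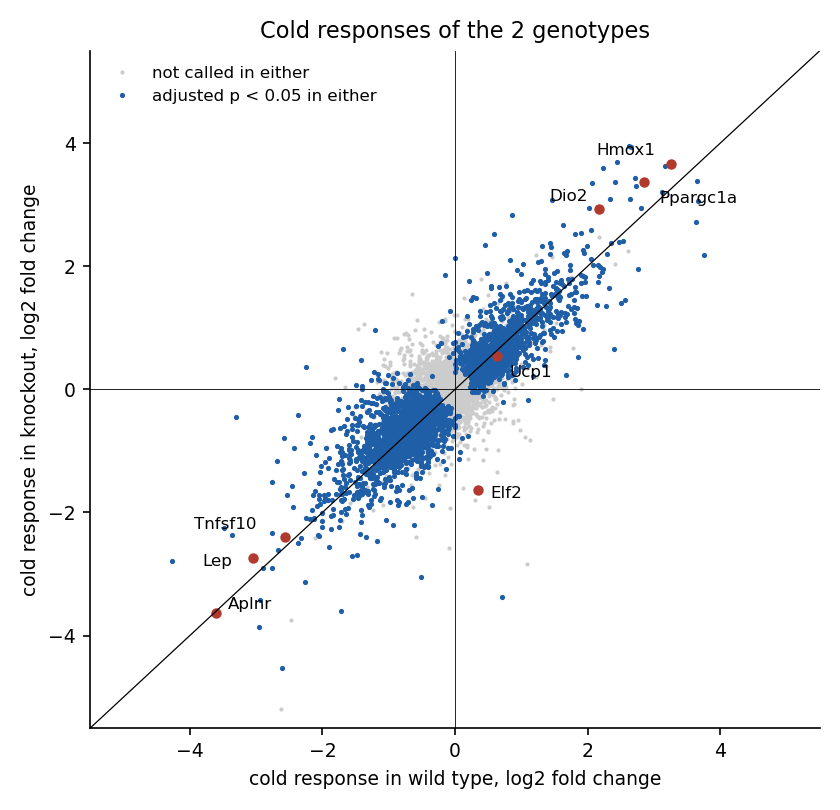
Log2 fold change in the cold in wild type (x axis) and knockout (y axis) for each tested gene, with genes called in either genotype in blue, genes called in neither in grey, named genes in red and a line of equal change. Most points follow the line, Elf2 lies off it at 0.34 and -1.63, and 3 genes fall outside the plotted range.

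The third comparison asked what loss of Noct changes at 22 °C. Few genes passed the threshold over all tested genes. Noct was lower in knockouts by -3.57 ± 0.53 log2 (adjusted p = 0.02). Ccdc144b, a coiled-coil gene on chromosome 3 (36007244 to 36053547) that was chosen after its values were seen, was lower as well (adjusted p = 0.00075). It had 441 counts over the 4 wild types and 2 counts over the 4 knockouts, a ratio of 165 (95% counting interval 45.5 to 1370). These were the 2 genes that passed in edgeR, with 486 at an unadjusted p below 0.05, and DESeq2 called 11. Thermogenic genes at 22 °C did not pass singly in edgeR. Ucp1 differed by 0.02 ± 0.16 (adjusted p = 0.998). Dio2 differed by -1.10 ± 0.23 (adjusted p = 0.357), with every knockout library (287 to 310 CPM) below every wild-type library (359 to 870 CPM). DESeq2 called Dio2 (-1.11, adjusted p = 0.00751). In simulated data with 200 changed genes DESeq2 called 25 unchanged genes for this comparison, a number that need not hold where few genes differ. Ppargc1a differed by -0.93 ± 0.33, and by -0.04 without wild-type 22 °C replicate 2. The Noct call was lost without wild-type 22 °C replicate 2 (-3.65, adjusted p = 0.19) or 4 (-3.43, 0.0512) and without knockout 22 °C replicate 1 (-3.47, 0.289) or 2 (-3.34, 0.0695), which left 1 gene each time. It was also lost with the replicate block, with sex (-4.01, 0.239) or without (-3.65, 0.0587), and with only the groups compared (-3.60, 0.579), and the call of Ccdc144b was lost in the first and last of these (adjusted p = 0.145 and 0.0503).

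As lists at 22 °C, 11 of 24 passed camera in the genotype comparison, and none did with an estimated correlation (3 at an unadjusted p below 0.05) or by fry (2 at an unadjusted p below 0.05). Lower in knockouts were the immediate-early (adjusted p = 8.07e-07, median -0.37), thermogenic (0.00394, -0.13), heat-shock (0.00626, -0.32), white adipocyte (0.00626, -0.42), macrophage (0.00659, -0.31) and fibroblast (0.0184, -0.11) lists. These had adjusted p = 0.347, 0.347, 0.447, 0.416, 0.447 and 0.447 with an estimated correlation. Higher were the nuclear-encoded oxidative phosphorylation (adjusted p = 2.42e-05, median 0.13), tricarboxylic acid cycle (5.32e-05, 0.15), mitochondrially encoded (0.00038, 0.28), NAD(P)(H) (0.00626, 0.16) and glycolysis (0.0137, 0.13) lists. These had adjusted p = 0.447, 0.416, 0.347, 0.447 and 0.447 with an estimated correlation. Scaling to total counts, from group means of log CPM without the sex term, moved the median of all genes from -0.002 to -0.18 log2. The medians of the 5 higher lists then lay above it (-0.062 to 0.118, negative in each but the mitochondrially encoded list) and those of the 6 lower lists below it (-0.809 to -0.307). Scaling and the sex term changed together here. By group means with DESeq2 size factors the median of all genes was -0.006, but that of the immediate-early list was -0.637. Mitochondrial genes took 52.1 ± 3.61% of counts in knockouts and 47.3 ± 1.57% in wild types at 22 °C. No member of these lists passed over all genes. Adjusted over the list alone, 1 thermogenic, 2 immediate-early and 1 fibroblast gene were lower. Without wild-type 22 °C replicate 2 the thermogenic (adjusted p = 0.0937) and heat-shock (0.415) lists did not pass. Without the sex term the glycolysis (0.0974), NAD(P)(H) (0.0524), heat-shock (0.0759) and white adipocyte (0.196) lists did not, and with the replicate block and sex glycolysis did not (0.112).

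In the cold, the genotype comparison asked what loss of Noct changes after 4 h at 6 °C. Elf2, a transcription factor of the ETS family, differed most clearly, at 30.5 ± 3.34 CPM in wild types (n = 5) and 5.03 ± 0.42 CPM in knockouts (n = 4), or -2.63 ± 0.12 log2 (adjusted p = 4.98e-10). It lies next to Noct on the opposite strand (chromosome 3, 51252720 to 51340663), with a gap of 1076 bp, and the strand setting of the counts is not known. Noct was lower by -4.11 ± 0.54 (adjusted p = 0.00218). Ccdc144b had 274 counts over the 5 wild types and 0 over the 4 knockouts, at least 70.9-fold lower against a floor of 3 counts over the group. Nudt6, a Nudix hydrolase gene on chromosome 3 (37404910 to 37420211) that overlaps Fgf2 on the other strand, was lower by -1.06 ± 0.17 (adjusted p = 0.0244). Nxnl1, a thioredoxin-like gene on chromosome 8 (71560555 to 71566601), was higher by 1.58 ± 0.27 (adjusted p = 0.0472). Nudt6, Nxnl1 and Ccdc144b were chosen after their values were seen. These 5 genes were all that passed in edgeR, with 393 at an unadjusted p below 0.05, and DESeq2 called 23. Ucp1 (-0.07 ± 0.15), Dio2 (-0.35 ± 0.24) and Ppargc1a (-0.41 ± 0.35) did not pass. The call of Nudt6 was lost without wild-type 22 °C replicate 2, 3 or 4, wild-type 6 °C replicate 1, 2, 4 or 5, knockout 22 °C replicate 1 or knockout 6 °C replicate 1, 2 or 3 (adjusted p from 0.0504 to 0.303). That of Nxnl1 was lost without any 1 of the 17 libraries but knockout 6 °C replicate 3 (adjusted p from 0.0603 to 0.337), and 3 genes were then the fewest that passed. Both calls were also lost with sex and age (adjusted p = 0.105 for Nudt6 and 0.131 for Nxnl1), with the replicate block and sex (0.719 each), with only the groups compared (0.794 and 1), against a fold of 1.5 (1 and 0.495), and from RPKM with a pseudocount of 1 (0.129 and 0.684) or 0.1 (0.0937 and 0.202). That of Nxnl1 was lost as well with no low-count filter (0.062), no sex term (0.078) and the block without sex (0.243).

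Heat-shock genes were lower as a list in knockouts at 6 °C (camera adjusted p = 1.15e-09, median -0.58, and adjusted p = 0.116 with an estimated correlation). None of its 12 members passed over all genes, and 8 were lower adjusted over the list alone. Hsph1 stood at 255 ± 60.4 CPM in wild types and 154 ± 64.1 CPM in knockouts (-0.77 ± 0.29), and Hsp90aa1 at 479 ± 111 and 319 ± 132 CPM (-0.78 ± 0.27). The clock list was lower as well (camera adjusted p = 0.000802, median -0.14, and adjusted p = 0.191 with an estimated correlation), with Per2 at -0.72 ± 0.26 and no member past the threshold on either adjustment. The other 22 lists did not pass, and fry called none of 24 (2 at an unadjusted p below 0.05).

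The last comparison tested whether the cold response differs between the genotypes. Elf2 passed in edgeR as the sole gene, with 310 at an unadjusted p below 0.05, and DESeq2 called 9 genes. Elf2 rose in wild type by 0.34 ± 0.10 (adjusted p = 0.0177), fell in knockouts (-1.63 ± 0.11, adjusted p = 5.06e-07), and the responses differed by -1.97 ± 0.15 (adjusted p = 2.54e-06). Its level at 22 °C was 24.1 ± 0.94 CPM in wild types and 15.6 ± 1.5 CPM in knockouts (-0.66 ± 0.12, adjusted p = 0.101), with every knockout library (13.4 to 16.9 CPM) below every wild-type library (23.1 to 25.2 CPM). DESeq2 called this difference (-0.66, adjusted p = 0.000458), and edgeR did so without the sex term (-0.63, 0.0379) and without wild-type 6 °C replicate 4 (-0.66, 0.0314). The difference between the responses was 0.76 ± 0.31 for Dio2, 0.52 ± 0.46 for Ppargc1a (0.02 to 0.76 when leaving out libraries, lowest without wild-type 22 °C replicate 2) and -0.08 ± 0.20 for Ucp1, each with adjusted p = 1. The Elf2 rise in wild type was lost without wild-type 22 °C replicate 2 (0.31, adjusted p = 0.0597) or wild-type 6 °C replicate 2 (0.32, 0.051). It was also lost with the replicate block and sex (0.32, 0.0592), with the majority sex alone (0.29, 0.115), against a fold of 1.5 (adjusted p = 1), and from RPKM with a pseudocount of 1 (0.10, 0.369) or 0.1 (0.13, 0.454). As lists, 12 of 24 passed camera for this difference. They included clock genes (adjusted p = 3.11e-05, median -0.26, and adjusted p = 0.159 with an estimated correlation) and heat-shock genes (adjusted p = 0.0294, median -0.32, and adjusted p = 0.472 with an estimated correlation). None of the 12 passed with an estimated correlation (1 at an unadjusted p below 0.05) or by fry (1 at an unadjusted p below 0.05).

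Genes associated with genotype gathered on chromosome 3, a count made after the values were seen. Among 21 genes at an unadjusted p below 0.001 in a genotype comparison, Noct left out, 8 lay within 20 Mb of Noct (38.1%), against 111 of all 12301 genes with a position (0.902%; Fisher's exact test, two-sided, p = 6.28e-12). Of these 8, 7 were lower in knockouts at both temperatures, among them Elf2, Nudt6, Ccdc144b, the glutathione transferase gene Mgst2 and the signalling inhibitor gene Spry1. The 6 that lay over 2 Mb from Noct were all on the same side of it, with starts from 36007244 to 41742611. Fisher's exact test takes genes as independent, which neighbouring genes need not be. Among 2086 genes called in both cold responses, 22 lay in the same window (1.05%, Fisher's exact p = 0.445).

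**Figure D4:**
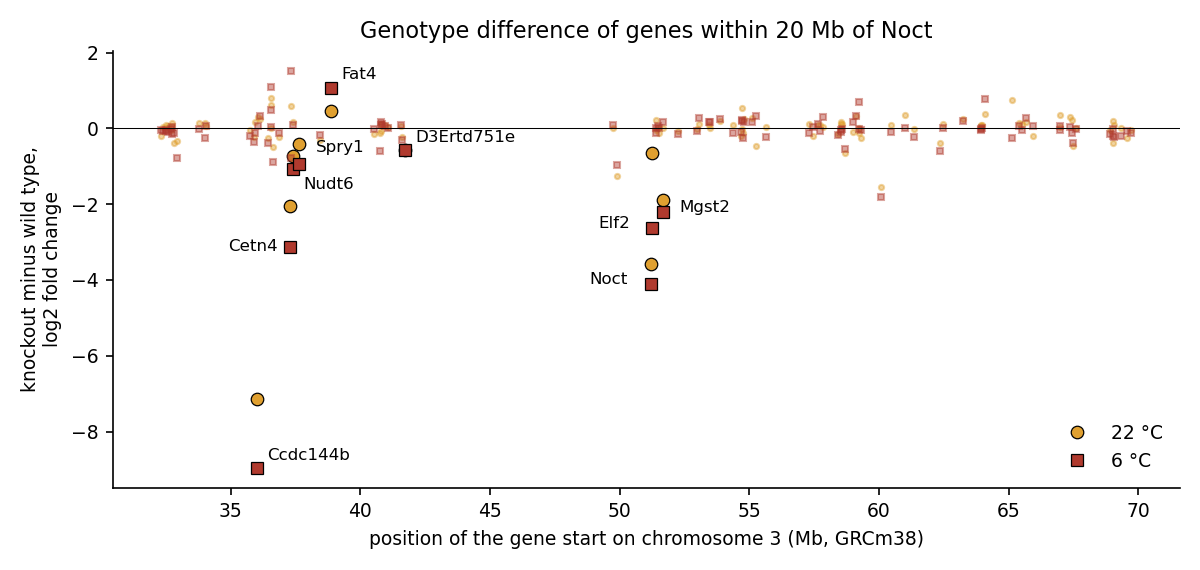
Log2 difference between knockout and wild type at 22 °C (circles) and 6 °C (squares) against gene start on chromosome 3 for tested genes within 20 Mb of Noct. Noct and the 8 genes at an unadjusted p below 0.001 have large outlined symbols and names, and of these 8 only Fat4 is higher in knockouts.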

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

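The tests of explanations and the counts of other splits of the samples were chosen after the results had been seen.

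Single libraries stood apart from the rest of their group in 27 of 364 tested group values, judged by the gap to the nearest library over the range. Chance gives about 1 in 20 for independent, normally distributed values, which CPM values need not be. Wild-type 22 °C replicate 2 was the highest of its group for 7 genes. They were Ppargc1a (493 CPM, others 92.4 to 116), Socs2 (17.5, others 4.04 to 5.29), Plk3 (12.1, others 3.38 to 4.48), Hmox1 (47.4, others 4.6 to 6.02), Mthfd2 (3.46, others 0.92 to 1.04), Hspa1a (0.981, others 0.197 to 0.228) and Hsph1 (81.4, others 44.9 to 49.5). Knockout 22 °C replicate 4, the library with the largest mitochondrial share (57.3%), stood apart for 8. It was the highest for Gk (350 CPM, others 207 to 220), Ucp1 (6090, others 4080 to 4390), Sqle (16.6, others 9.88 to 9.97), Hsd17b7 (14.6, others 7.35 to 8.44), Idh1 (199, others 170 to 174), Dnajb9 (52.4, others 47.6 to 48.3) and Ccdc144b (0.0833, others 0), and the lowest for Slc2a1 (1.71, others 2.79 to 2.95). For Ccdc144b, 2 counts against 0 in the others set it apart by construction. Knockout 22 °C replicate 3 was the highest for Mfsd2a (19.6 CPM, others 5.57 to 6.83), Hmox1 (19.2, others 4.16 to 5.79), Per2 (20.2, others 11.2 to 12) and Mt2 (41.8, others 18.8 to 22.5). Knockout 6 °C replicate 1 was the highest for Sqle (35.9 CPM, others 10.5 to 14.3) and Bhlhe40 (49.3, others 20 to 23.1). Knockout 6 °C replicate 4 was the highest for Hcar1 (12.4 CPM, others 1.77 to 2.75). Wild-type 22 °C replicate 1 was the highest for Ccdc144b (5.04 CPM, others 1.9 to 2.3) and the lowest for Acsl1 (2060, others 2790 to 2910). The lowest of their groups were also wild-type 6 °C replicate 4 for Kcnk3 (563 CPM, others 676 to 719), knockout 6 °C replicate 3 for Idh1 (87.9, others 116 to 119) and knockout 22 °C replicate 2 for Cd163 (3.37, others 7.38 to 8.08).

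Wild-type 22 °C replicate 2 lay toward the cold libraries, by a median 0.274 of the way for 811 cold-raised genes and 0.229 for 601 cold-lowered genes. A cold animal under a 22 °C label is argued against, since 0.274 lies below the lowest wild-type cold library measured the same way (0.57, replicate 4). RNA or reads of a cold library mixed in would give raised and lowered genes 1 fraction, and the difference of 0.045 was smaller than the largest among the other 3 libraries (-0.129), so a mixture is a candidate explanation. The male sex of this mouse cannot be told apart, because males exceeded females by 0.074, 0.032 and 0.32 in the other groups, with a single male or female in each. No other biological explanation was tested.

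Elf2 was lower in knockouts, and the cold responses of the genotypes differed for it (-1.97 ± 0.15 log2). Reads of Noct counted for Elf2 are argued against, since Elf2 changed by 0.0131 CPM per CPM of Noct within the wild-type groups (-0.0211 to 0.0317 when leaving out each library), below the 0.0675 and 0.0788 that the genotype differences would need. Library depth or composition is argued against by the 500 genes nearest in level, which it would lower alike. Their median difference between the responses was -0.01 (SD 0.19), a value that TMM scaling itself keeps small. But the lowest of them was -0.63, and scaling to total counts moved the median of all genes to 0.119 only. A change of the Elf2 locus carried with the targeted allele and an effect of Noct loss itself stay open too, since each follows genotype.

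The 8 genotype-associated genes within 20 Mb of Noct on chromosome 3 were out of proportion to the 111 tested genes there (Fisher's exact p = 6.28e-12, from a test that takes neighbouring genes as independent). An effect of the targeted allele on its direct neighbours is argued against for most of them, as 75% lay over 2 Mb away. A stretch of chromosome 3 inherited with the targeted allele may account for them, a hypothesis found and tested on the same data that Ccdc144b, 15.2 Mb from Noct, fits by position. Loss of Noct acting on these genes stays open, as the design has no other allele.

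In 12 lists the cold response differed between genotypes by camera. The response was more positive in knockouts for the immediate-early list (adjusted p = 0.00104, and adjusted p = 0.409 with an estimated correlation), the white adipocyte list (0.0467, and adjusted p = 0.472 with an estimated correlation) and the macrophage list (1.79e-05, and adjusted p = 0.409 with an estimated correlation). It was more negative for glycolysis (0.0261), the tricarboxylic acid cycle (1.79e-05), nuclear-encoded oxidative phosphorylation (8.28e-05), mitochondrially encoded subunits (0.00626), fatty acid oxidation (0.00626) and sterol synthesis (0.0294). With an estimated correlation these had adjusted p = 0.566, 0.409, 0.472, 0.409, 0.409 and 0.566, in the same order. It was also more negative for clock genes (3.11e-05), NAD(P)(H) genes (0.04) and heat-shock genes (0.0294), which had adjusted p = 0.159, 0.501 and 0.472 with an estimated correlation. Scaling to total counts, from group means of log CPM without the sex term, moved the median of all genes from -0.003 to 0.119 log2. The medians of the 9 lists with a more negative response, for which scaling and sex term changed together, then lay between -0.171 and -0.009. Each still lay below the median of all genes. The white adipocyte list did not pass without the sex term (0.0797) or without wild-type 22 °C replicate 2 (0.0645), nor did glycolysis (0.0639), NAD(P)(H) (0.0594) or heat-shock genes (0.057) with the replicate block and sex.

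Chance was excluded by other splits for the cold response in wild type, where 1 of 100 splits, the real one, gave as many as 3450 genes. The highest of the others, at 2814, had 8 of the 9 samples relabelled and so nearly mirrored the real split. In knockouts 1 of 35 splits, the real one, gave as many as 2697 genes for the cold response (highest other 93). As no smaller share can be reached with 35 splits, this argues against chance without excluding it. For the genotype difference at 22 °C, 1 of 35 splits gave as many as 2 genes (highest other 1), which argues against chance for a count that includes the targeted gene Noct. With Noct not counted, 3 of 35 splits gave 1 gene (highest other 1), so chance was not excluded for the number of genes beside it. Judged by the strongest gene, Ccdc144b, 1 of 35 splits, the real one, gave an adjusted p as low as 0.00075 (lowest other 0.00187). That is the smallest share 35 splits can reach, and alternatives lost this call, so it argues against chance without excluding it. Chance was not excluded for the number of genes in the genotype difference at 6 °C, where 5 of 100 splits gave 5 genes or more (highest other 942). Nor was it for the number in the difference between the cold responses, where 8 of 100 gave 1 gene or more (highest other 134). Splits with that many more genes than the real one point to a structure of the samples, and what it follows was not tested. These counts weigh genes of any strength alike. Judged by the strongest gene, Elf2 in both comparisons, chance was excluded. At 6 °C 1 of 100 splits, the real one, gave any gene an adjusted p as low as 4.98e-10 (lowest other 0.0113), and for the difference between the responses 1 of 100 gave one as low as 2.54e-06 (lowest other 0.005). At 6 °C the calls of Noct and Ccdc144b held whichever library was left out (adjusted p up to 0.0376 and 0.00993), although Ccdc144b was not called from log2(RPKM + 1) (adjusted p = 0.824), and those of Nudt6 and Nxnl1 did not hold.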

How the results depend on the processing

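Of the tests here, those without mitochondrial genes, the list tests without wild-type 22 °C replicate 2, the correlations leaving out libraries and the alternatives for the sex difference were chosen after the data had been seen. Of 166 results for named genes, 162 kept their direction under every setting run, and of the 154 past the threshold 121 kept the call whichever library was left out. The cause was not tested where a value below differs, unless fewer samples or a stricter test explain it by construction. Against a fold of 1.5 (glmTreat), 381 genes passed for the cold response in wild type, 340 in knockout, 3 for genotype at 6 °C and 4 for sex, against 3450, 2697, 5 and 8. Only the groups compared gave 1589 for the cold response in knockout, 0 for genotype at 22 °C (508 at an unadjusted p below 0.05, edgeR) and 3 for genotype at 6 °C. The difference between the responses needs all groups, so this setting gave it no value. The majority sex alone gave 1647 in knockout. DESeq2 gave 11 for genotype at 22 °C, 23 at 6 °C, 9 for the difference between the responses and 40 for sex, against 2, 5, 1 and 8. Of its 11, 23 and 9 genes, 10, 12 and 1 were tested in edgeR. In simulated data with 200 changed genes it called 25, 17 and 22 unchanged genes in these comparisons, and edgeR 5, 3 and 5. The adjustment admits more false calls where more genes pass, so these numbers need not hold where few genes differ. At 22 °C, genotype gave 4 genes without the sex term, 0 with the replicate block and sex (472 at an unadjusted p below 0.05, edgeR), 1 with the block and no sex term, and 4 from RPKM with either pseudocount. At 6 °C it gave 3 with sex and age and 3 from log2(RPKM + 1). Sex gave 14 with age and 1 with the block.

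Leaving out libraries gave 1 to 3 genes for genotype at 22 °C (1 without wild-type 22 °C replicate 2 or 4 or knockout 22 °C replicate 1 or 2) and 3 to 5 at 6 °C. The 3 came without wild-type 22 °C replicate 2, 3 or 4, wild-type 6 °C replicate 1, 2, 4 or 5, knockout 22 °C replicate 1 or knockout 6 °C replicate 1 or 2. Sex gave 4 to 14. The correlation of the cold responses was 0.744 to 0.825, and 0.902 over genes called in either. Of the lists, 0 passed with an estimated correlation in each comparison (2, 3, 3, 2 and 1 at an unadjusted p below 0.05, in the order of the comparisons). By fry 6 passed for the cold response in wild type, and 0 for genotype at either temperature and for the difference between the responses. With the replicate block 5 passed for the cold response in wild type, as did 5 without wild-type 22 °C replicate 2, and without the sex term 4 passed for genotype at 6 °C.

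Reversed signs were seen for values that passed no test. Ucp1 by genotype at 22 °C (0.02) was -0.05 with the replicate block and sex, 0 with only the groups compared, -0.14 from RPKM with either pseudocount, and -0.1 to 0.09 when leaving out libraries, and at 6 °C (-0.07) it was -0.17 to 0.02. The difference between the responses for Ucp1 (-0.08) was 0.06 from RPKM with either pseudocount and -0.15 to 0.06 when leaving out libraries. For Noct (-0.54) it was 0 from log2(RPKM + 0.1) and -0.87 to 0.59 when leaving out libraries, the highest without knockout 22 °C replicate 3. The replicate numbers did not pair the samples, since 4 of 17 correlated best with a sample of their own number. For Ccdc144b, depth limits the fold, since the counts of 2 and 0 in knockouts allow an interval and a bound only. In simulated data, 16.4% of genes changed by a fold of 1.5 were recovered for genotype at 22 °C.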

Other observations

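The comparison of the sexes was planned as a description of the covariate, its alternatives and the genes named were chosen after the data had been seen, and no explanation was tested in this part.

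Between the sexes, 8 genes passed in edgeR over all groups. The Y-linked genes Ddx3y (6.86 log2), Eif2s3y (6.87), Kdm5d (6.75) and Uty (6.96) were higher in males. The X-linked demethylase Kdm6a was lower (-0.73), the oxytocin receptor gene Oxtr was lower (-2.42), and the imprinted gene Nnat (3.19, adjusted p = 0.0286) and the complement gene C7 (1.96, adjusted p = 0.0239) were higher. Counts of Ddx3y were at least 1831 in mice labelled male and at most 114 in mice labelled female. Of the lymphocyte markers 3 were tested, too few for a list test. Among them Cd4 read -0.68 ± 0.40 log2 in the cold in wild type and 0.45 ± 0.43 in knockouts, neither past the threshold.

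The first principal component held 33.0% of the variance of log CPM and put every 22 °C library (-35.87 to -15.57) below every 6 °C library (12.25 to 42.23). The second held 19.9%, and its highest libraries were knockout 22 °C replicate 4 (35.37) and knockout 6 °C replicate 3 (39.41). These had the largest mitochondrial shares (57.3% and 57.0%) and high summed muscle levels (1132 and 1572 CPM). The lowest were wild-type 22 °C replicate 4 (-37.34) and knockout 6 °C replicate 2 (-37.06). These had the lowest summed muscle levels (32.0 and 23.5 CPM), whereas their mitochondrial shares (48.9% and 51.6%) were not the lowest. Noct counts in knockouts ran from 81 to 895 per library, above a count of 0 in each. The highest was knockout 22 °C replicate 3, at 34.2 CPM.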
